A study of Mus musculus with 8 samples.

How the data were processed

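H3K27me3, the repressive histone mark placed by Polycomb repressive complex 2, was profiled by ChIP-seq in mouse embryonic stem cells. Per the labels, 2 clones (A and B) of the E14tg2a line stably expressed a cRAF-ErT2 fusion, a RAF kinase that is switched on by 4-hydroxytamoxifen (4OHT) and drives ERK signalling. Cells were grown in serum with LIF and 2 µM Chir99021, a GSK3 inhibitor, and then for 24 h in serum and LIF with 250 nM PD173074, an FGF receptor inhibitor. They were taken untreated (0 h) or after 2 h of 250 nM 4OHT. Chromatin was fixed with 1% formaldehyde for 10 min. The series has 8 samples in 4 groups of 2. The table used here carries the 4 H3K27me3 libraries, and the 4 input libraries were not analysed.

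The authors deposited whole-number read counts per interval, per the file headers, where an interval spans an annotated transcript from start to end with its introns. Per the submitters' processing notes, Bowtie2, bedtools and the build mm10 were used; versions, filters and counting options are not given in the sources used here. The table holds 50398 intervals on chromosomes 1 to 10, X, Y and M, and intervals on other chromosomes were not analysed here. A further 12 unnamed per-library columns derived from the counts were not used. Of the intervals, 84.8% overlap another one, so a read can be counted several times and a column total is not a sequencing depth. Column totals were 70378127 (0 h, clone A), 81279899 (0 h, clone B), 92518605 (2 h, clone A) and 85062523 (2 h, clone B). Counting ignores strand and transcript, so overlapping genes and isoforms share reads.

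Intervals were given gene symbols by overlap with RefSeq genes of GRCm38.p6, the assembly that mm10 stands for. A name was given at an overlap of at least 0.5 of the union and at least 0.2 more than the next gene. This named 43790 intervals (86.9%) and 20225 genes. Values per gene come from 1 interval. This overlap replaced the nearest transcription start that had been planned. Density is the count per kb per 1000000 counts of the column total. A gene was called marked at 4 times the median gene density (0.357) or more. This measure was chosen after seeing the data, in place of enrichment over input. Genes shorter than 1000 bp were marked more often than longer ones (9.96% against 5.51%), a share that includes microRNA genes. Lists were therefore set against length-matched random lists.

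The comparison of 2 h with 0 h used edgeR 4.0.16 quasi-likelihood tests on the counts, with TMM factors and filterByExpr, which left 50037 intervals; Benjamini-Hochberg adjusted p-values were read at 0.05. SE is the standard error of the log2 change. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and Benjamini-Hochberg adjusted over 14 lists: ERK-responsive, naive pluripotency, general pluripotency, formative and primed epiblast, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, PRC1 and PRC2 subunit, housekeeping, fibroblast, germline, Hox cluster and olfactory receptor genes. The lists, the tests of treatment and the rule for named genes were fixed before the data were examined. The rule named every measured gene of a panel of 26, the 5 intervals per direction with the smallest p that moved the same way in both clones (since none passed), and up to 4 members per list with the highest average count. The value of 1 panel gene is not reported here. The genes of highest density replaced those highest over input, a choice made after seeing the data. Alternatives were DESeq2 1.42.0, other factors and filters, clone as a block, and leaving out each library. Shares of marked genes were compared with Fisher's exact test in SciPy 1.17.1, two-sided. Input comparisons, enrichment over input, the input-adjusted interaction and gene lists over input were planned and not run. R 4.3.3 and Python 3.11.15 were used.

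The same clones were sampled at both times, per the labels, so clone letters pair the libraries. The 2 libraries of a clone deviated together from their time means (r = 0.514 across 50037 intervals, which are not independent replicates; r = 0.687 across the 42201 intervals with a mean count of at least 100). The tests were checked on simulated counts for the 50037 intervals with 50 changed intervals per fold size. Without the block, 4% of 2-fold and 30% of 3-fold changes were recovered, and with the block 54% of 1.25-fold, 78% of 1.5-fold and 98% of 2-fold changes. The block gave 9 false calls and the other fit 0. The simulated spread followed count level alone, and the simulated counts held no trend over density that differs between the clones over time. Each group holds 2 libraries, and the clones come from 1 line, so p-values measure the spread between these samples, which may be technical. All counts are of reads without molecular identifiers.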

Results

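The data comprised H3K27me3 ChIP-seq counts over transcript intervals for untreated stem cells (0 h) and cells with 2 h of RAF-ERK activation by 4OHT, each in clones A and B (n = 2 libraries per time). Column totals ranged from 70378127 to 92518605 counts. The median interval held 427 to 558 counts. Log2 counts of the 2 libraries of a clone correlated at 0.996 (clone A) and 0.997 (clone B) across intervals, and those of different clones at 0.992. These counts were not divided by interval length, which ran from 51 to 2390387 bp. Length is shared by all libraries and raises each correlation, so the values do not measure how well the mark itself was reproduced.

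The first question was which genes carried H3K27me3 in these cells. The mark was densest over the Hox clusters and over regulators of later lineages, and sparse over genes used by stem cells and by all cells. All 20 measured Hox genes, which pattern the body axis, were marked, with a median density of 4.50 ± 0.355 counts per kb per 1000000 counts (SD of the list median over 4 libraries). Neuroectoderm genes followed at 3.71 ± 0.298, with 18 of 19 marked. Housekeeping genes stood at 0.0879 ± 0.00697 and general pluripotency genes at 0.0878 ± 0.0109, with 0 of 11 and 0 of 9 marked. With only 5.47% of other coding genes marked, these shares did not pass Fisher's exact test. Their medians lay at percentiles 0.10 and 0.24 of length-matched random lists. The densest members were B2m (2.48 times the median gene) and Utf1 (3.07).

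Among coding genes of at least 1000 bp, Hoxa6 (chromosome 6, 52206365 to 52208624, mm10) had the highest density. It measured 5.68 ± 0.858 at 0 h and 5.46 ± 0.638 at 2 h (SD, n = 2), 15.6 times the median gene. Hoxd10, Hoxa9, Hoxd13, Hoxd12 and Hoxa10 lay between 14.7 and 15.4 times the median. Outside the Hox clusters, Id3, an inhibitor of helix-loop-helix factors, reached 14.8 times the median, as did Atoh1, a neural fate regulator, and Skor1. Gm46725, also among the 10 densest, lies beside Bmi1 on chromosome 2. These intervals overlap or adjoin one another within the clusters, so their counts are partly shared.

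Lists varied in the share of genes marked, but their densities overlapped widely: 0.35 to 14.1 times the median gene for mesendoderm and 0.53 to 14.3 for trophectoderm. No test compared the lists with each other. Mesendoderm genes had 7 of 12 marked and a median of 1.95 ± 0.139, with Foxf1 at 14.1 and Eomes at 6.33 times the median gene. Trophectoderm genes had 5 of 10 marked and a median of 1.49 ± 0.0189; Cdx2, a trophectoderm regulator, stood at 14.3 times, Gata2 at 10.3 and Gata3 at 4.82. ERK-responsive genes had 4 of 11 marked, among them Egr2 (5.39 times), Fosb (5.07) and Atf3 (4.63), while Dusp6, an ERK phosphatase, stood at 1.23. Formative and primed epiblast genes had 3 of 7 marked, with Pou3f1 at 11.2 and Fgf15 at 8.99 times and Fgf5 at 2.81. For Hox, neuroectoderm, mesendoderm, trophectoderm, ERK-responsive and formative genes, the share marked was above that of other coding genes (two-sided Fisher's exact test, adjusted p over 14 lists from 6.13e-25 for Hox to 0.00964 for formative genes). Their medians lay at or above percentile 99.2 of 10000 length-matched random lists. Hox genes lie in clusters and their intervals partly overlap, as Hoxa6 lies within the Hoxa3 interval, so they are not independent. Both comparisons counted each gene separately, so the p-value and percentile of the Hox list overstate the evidence. The same limit holds for neighbouring genes in any other list.

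Primitive endoderm genes had 2 of 11 marked (adjusted p = 0.207) with a median at percentile 98.9 of random lists, led by Sox17, an endoderm regulator, at 12.3 times the median; Pdgfra stood at 2.65 and Col4a1 at 2.16. Fibroblast genes had 1 of 12 marked and germline genes 1 of 9 (adjusted p = 0.605 for both), with medians at percentiles 93.1 and 85.8; Twist2 stood at 3.14 and Mael at 1.80 times the median. Olfactory receptor genes, silent in most tissues, had 3 of 749 marked, below the 5.77% of other coding genes (adjusted p = 1.97e-14), with a median at percentile 8.66.

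Naive pluripotency genes had a median of 0.113 ± 0.00930, at percentile 2.37 of random lists. Nanog stood at 0.694 times the median gene, Tbx3 at 0.532, Klf4 at 0.334 and Tet2 at 0.245. The 1 marked member of 13 was Dppa3, at 5.45 times. PRC1 and PRC2 subunit genes had a median of 0.0961 ± 0.00771, and Ezh2, the methyltransferase of PRC2, stood at 0.260 times the median. Bmi1, a PRC1 subunit, was the 1 marked member of 11, at 11.8 times. Sox2 stood at 0.304, Actb at 0.272 and Gapdh at 0.183 times. In all, 1170 of 20225 genes (5.78%) were marked, and 3815 or 402 at limits of 2 or 8 times the median.

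**Figure D1:**
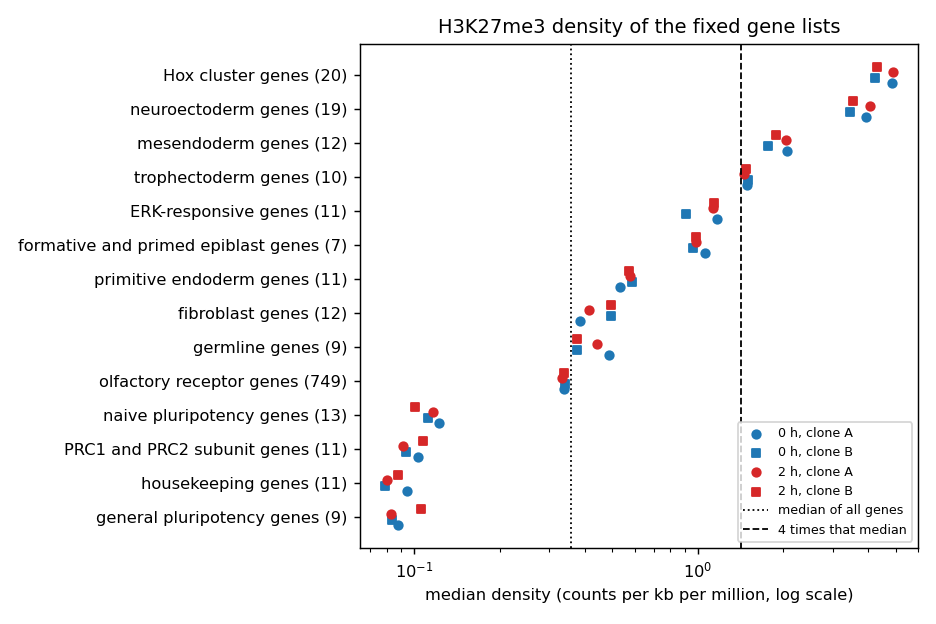
Median H3K27me3 density of each fixed gene list (number of genes in brackets) on a log axis in counts per kb per 1000000 counts, with 1 point per library; the dotted line is the median of all genes and the dashed line 4 times that. The Hox, neuroectoderm, mesendoderm and trophectoderm lists lie right of the dashed line in all 4 libraries. The housekeeping, general pluripotency, naive pluripotency, PRC and olfactory receptor lists lie left of the dotted line.

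The second comparison asked whether H3K27me3 changed within 2 h of RAF-ERK activation. No interval passed the test in either direction. Counts were taken over whole transcripts (median interval 20477.5 bp), so a change confined to a promoter could be diluted. Sox17 measured 4.49 ± 0.507 at 0 h and 4.28 ± 0.565 at 2 h, a log2 change of −0.07 (SE 0.14, n = 2 per time; −0.03 in clone A and −0.12 in clone B). Cdx2 measured 5.07 ± 0.725 and 5.14 ± 0.511, and Pax6, an eye and forebrain regulator, 2.92 ± 0.0567 and 2.88 ± 0.00998 (−0.02 in A and −0.03 in B). edgeR called 0 higher and 0 lower of 50037 intervals, with 188 (0.38%) at an unadjusted p under 0.05. That share is below what the threshold gives with no change, so this unpaired test was conservative. With clone as a block it was 4.15%. DESeq2 called 0, with 2 at that level.

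Of the panel, 15 genes were measured and none passed. The log2 changes were 0.02 for Cdx2, 0.03 for Eomes and Pdgfra, −0.03 for Pax6, −0.04 for Fgf5 and −0.14 for Hoxd13. Nanog gave 0.01, Tbx3 −0.04, Klf4 0.23 and Sox2 0.26. The housekeeping genes Actb and Gapdh, with few counts, gave −0.49 (SE 0.30) and 0.08 (SE 0.32). Dusp6 (chromosome 10, 99263231 to 99267489) had the largest positive value of the panel, 0.34 (SE 0.15), from a density of 0.386 ± 0.0309 to 0.491 ± 0.00108. It was higher at 2 h in both clones (0.45 in A and 0.24 in B), and its adjusted p rounded to 1. In the paired fit the 95% intervals, unadjusted for the number of tests, were 0.04 to 0.64 for Dusp6 and −0.27 to −0.01 for Hoxd13, and neither gene passed there.

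**Figure D2:**
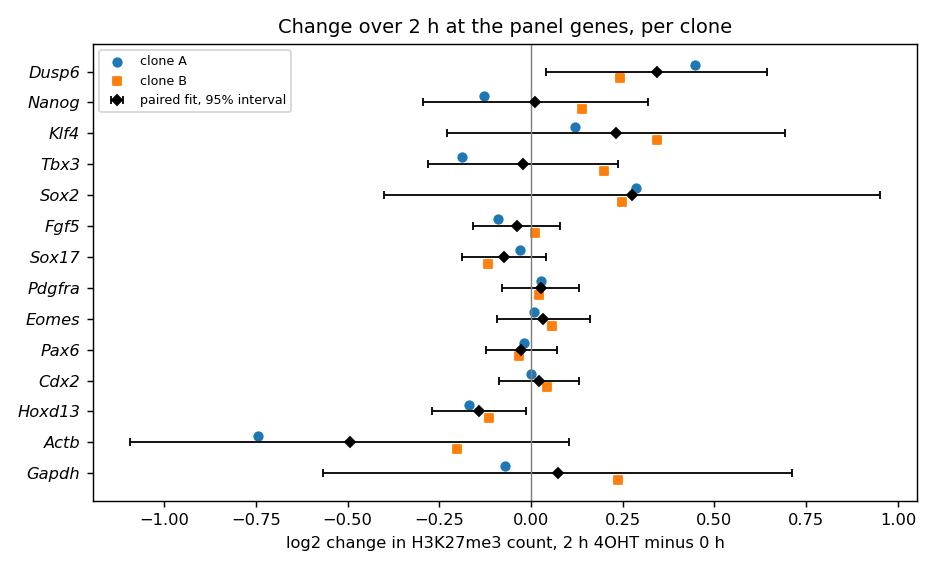
Log2 change in H3K27me3 count from 0 h to 2 h at panel genes, with circles for clone A, squares for clone B, and diamonds with bars for the estimate of the paired fit and its 95% interval. The marked genes Sox17, Eomes, Pax6 and Cdx2 have intervals that include 0, those of Dusp6 and Hoxd13 exclude it before adjustment for the number of tests, and Actb, Sox2 and Gapdh, with few counts, have the widest.

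Gene lists gave small shifts. With the preset correlation, ERK-responsive genes passed as higher (adjusted p = 0.00892 by camera on the edgeR fit), with a median change of 0.13 over 11 genes; 5 were higher and 1 lower in both clones. This list did not pass with an estimated correlation (adjusted p = 0.557 with an estimated correlation). Fosb, an immediate early gene, gave 0.16 (SE 0.11), Atf3 0.04, Dusp4 0.01 and Egr2 −0.02. Formative and primed epiblast genes also passed as higher (adjusted p = 0.0214, median 0.04), but not with an estimated correlation (adjusted p = 0.855), with Pou3f1 at 0.12 and Lef1 at 0.01. Olfactory receptor genes (median −0.03), PRC1 and PRC2 subunit genes (−0.08) and germline genes (−0.05) passed as lower (adjusted p = 0.00555, 0.00555 and 0.0214), with Bmi1 at −0.12, Ezh2 at −0.11 and Mael at −0.10. These 3 lists did not pass with an estimated correlation either (adjusted p = 0.557, 0.855 and 0.855), and fry called none of the 14 (lowest adjusted p 0.661). Both tests rest on 2 residual degrees of freedom, which limits their power. How large a shift they could detect was not simulated. The estimated correlation was −0.058 for ERK-responsive and 0.0056 for olfactory receptor genes, below the preset 0.01. For these 2 lists a higher correlation did not end the call, and the losses do not decide whether they shifted. For formative, PRC and germline genes the estimate was 0.190, 0.399 and 0.478, well above the preset. A preset of 0.01 may therefore overstate the calls of these 3 lists. With 1 interval per gene, formative, PRC and germline genes did not pass at the preset correlation (adjusted p = 0.663, 0.297 and 0.403). Each of the 5 also lost its call without at least 1 library. ERK-responsive genes lost it without any single library, and formative and olfactory receptor genes without clone B at 0 h or either 2 h library. PRC genes lost it without clone A at 0 h or either 2 h library, and germline genes without clone A at 0 h or clone B at 2 h. Such a fit leaves 1 time with a single clone, so time and clone are confounded and the losses do not decide.

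The other 9 lists did not pass. With 1 library left out, Hox and neuroectoderm genes leaned lower without clone B at 0 h or clone A at 2 h. Naive pluripotency genes did so without clone B at 0 h, and fibroblast genes without clone A at 0 h. These fits also confound time with clone, so no call over time is read from them. In the comparison of clones, 18 of 20 Hox and 15 of 19 neuroectoderm genes were called higher in clone A and 0 lower. A higher level in clone A gives this direction for both lists without a change over time. Median changes were −0.08 for naive pluripotency, 0.14 for general pluripotency, −0.01 for primitive endoderm, 0.04 for mesendoderm, 0.00 for neuroectoderm, 0.02 for trophectoderm, 0.05 for housekeeping, −0.00 for fibroblast and −0.02 for Hox genes. For trophectoderm and neuroectoderm genes the test pointed lower and for primitive endoderm genes higher, against the sign of the median. No member of any list passed, over all intervals or adjusted over the list alone. With clone as a block, neuroectoderm genes also passed as lower (adjusted p = 0.0330; 0.883 with an estimated correlation). In the paired fit 1 formative and primed epiblast gene, Dnmt3b, a DNA methyltransferase named after its values were seen, passed when adjusted over the list alone, at 0.27 (SE 0.08, adjusted p = 0.00940) and 0.26 in its 2 intervals, but not over all intervals.

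The intervals of smallest p were poor in counts and did not pass. Gm6268 had 8 and 8 counts at 0 h and 26 and 19 at 2 h. Gm20199 gave a log2 change of 1.06, Actrt1, an actin-related gene, 1.03 and Snapc2 0.84. Gm46943 gave −1.30, Kis2 −1.17, Gm15133 −0.88, Gm39172 −0.85 and C330018A13Rik −0.54. Gm46943 had 27 and 30 counts at 0 h and 12 and 15 at 2 h.

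Over all marked genes, the change relative to other genes was 0.05 in clone A and −0.00 in clone B, a mean of 0.03 ± 0.04 (SD, n = 2 clones). No test was run on these 2 values. Of 1160 marked genes tested, 956 (82.4%) had a 95% interval of the change within 1.5-fold either way, and 1078 (92.9%) in the paired fit. Fitted with the block on marked intervals alone, a choice made after seeing the data, 22 of 2468 intervals were called higher and 56 lower; with factors from all intervals the split was 8 and 0. Simulations without the block recovered 4% of 2-fold changes, so that fit could miss such changes. With the block 98% were recovered in simulated counts, and the paired fit of the data called 0 of 50037 intervals. The simulated spread followed count level alone, so recovery in the data may be lower. Gm46943 (−1.30) and Gm20199 (1.05), with few counts, did not pass in the paired fit, so 2-fold changes are not excluded.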

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

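The test of paired calls among marked intervals was chosen after those results were seen; the random-list tests were set out before theirs. Clones A and B went opposite ways over 2 h in several summaries, and with 1 library per clone and time these differences were not tested. Among general pluripotency genes the median log2 change was −0.15 in A and 0.31 in B (difference −0.46), and among housekeeping genes −0.15 and 0.18 (−0.33). Formative and primed epiblast genes gave −0.01 and 0.15 (−0.16), primitive endoderm genes 0.03 and −0.05 (0.0761) and fibroblast genes 0.01 and −0.03 (0.0438). Neuroectoderm genes gave 0.01 and −0.02 (0.0315) and trophectoderm genes 0.02 and −0.01 (0.0339). The level over marked genes relative to others gave 0.05 and −0.00 (0.0551). With genes in 10 groups by density, the change in the densest group minus that in the least dense was 0.12 in A and −0.16 in B (0.28).

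The opposite medians of general pluripotency and housekeeping genes were weighed against a trend over density that differs between the clones. Both lists sit among the least dense genes, where the median change was −0.05 in A and 0.15 in B. The median over genes of clone A minus clone B was −0.24 for general pluripotency genes, at percentile 38.5 of 10000 random lists matched on density and length, and −0.31 for housekeeping genes, at percentile 14.7. Both are consistent with a change shared by genes of low density, as background reads may give. Whether the trend came from the immunoprecipitation, the library or the cells stays open, since each clone and time has 1 library.

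The paired calls among marked intervals (22 higher and 56 lower) were weighed against overlapping intervals. With factors from all intervals they were 8 and 0, so the balance of higher and lower calls depends on the centring, and no direction is read from it. The 78 called intervals held 39 named genes, of which 7 (17.9%) were called when 1 interval per gene was fitted. Those, named after their values were seen, had log2 values relative to the other marked intervals of 0.26 (Tmem200b), 0.43 (Gm10013), −0.37 (Gm46069), −0.21 (Gm46729), −0.18 (Cdx4), −0.18 (Cdkn2c) and −0.15 (Bmi1). A biological change of this size at these genes stays open.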

How the results depend on the processing

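The DESeq2 test called 0 intervals between 2 h and 0 h (2 at an unadjusted p under 0.05), and so did edgeR with DESeq2 size factors, column totals, no filter on low counts, a mean count of at least 50, an adjusted p under 0.1, or clone as a block (0 higher and 0 lower, 2078 at an unadjusted p under 0.05). Leaving out each library gave 0 higher and 0 to 1 lower; the 1 call, without the clone A library at 2 h, was an interval on chromosome 2 (157558362 to 157562525; log2 −1.28, adjusted p = 0.0423 by edgeR) that overlaps Nnat and Blcap. Its counts were 237 and 311 in clone A and 91 and 79 in clone B, so without that library, which leaves clone B alone at 2 h, time and clone are confounded there. Settings added after seeing the data also gave 0 with factors from sparse or marked intervals, the factors of the file header, 1 interval per gene with or without the block, and adjustment over marked intervals alone. Fitted with the block on marked intervals alone, calls were 22 higher and 56 lower, 8 and 0 with factors from all intervals, and 2 and 5 with 1 interval per gene. With 1 interval per gene and the limit also moved, they were 5 and 3 at 8 times the median density and 0 and 0 at 2 times. Camera called 2 lists higher and 3 lower, 2 and 4 with the block, and 1 and 1 with 1 interval per gene. It called 0 and 0 with 1 interval per gene under the block, and with an estimated correlation (also with the block or 1 interval per gene). Fry also called 0 and 0. Camera with an estimated correlation and fry rest on 2 residual degrees of freedom, or 1 with the block, which limits their power. That power was not simulated. Leaving out a library gave 0 to 1 lists higher and 0 to 5 lower; the sign turned, with no call, for formative genes without clone B at 0 h (adjusted p = 0.609; range 1.28e-05 to 0.609), PRC genes without clone A at 0 h (0.870; 1.45e-05 to 0.870) and germline genes without clone A at 0 h (0.691) or clone B at 2 h (0.918; 8.78e-05 to 0.918). The cause was not tested. Marked genes numbered 3815 and 402 at 2 and 8 times the median, and 1129 to 1201 without each library. Clone A exceeded clone B in 8633 intervals and fell below it in 5132; 1 interval per gene, with fewer tests, gave 3181 and 2110, and removing the trend over density 8090 and 7927. Input comparisons, enrichment over input, its interaction and lists over input were not run, as input libraries were not analysed. With 1 interval per gene the block ended the calls of ERK-responsive (adjusted p 0.0410 to 0.0618) and olfactory receptor genes (0.0116 to 0.0618). On all intervals with the preset correlation, it added the neuroectoderm list and, adjusted over the list alone, the Dnmt3b intervals, and changed no other call.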

Other observations

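The families, the X chromosome values, the clone comparison, its density test at 1.5-fold and the imprinted-gene test were chosen after the data were seen; the segment, Hox and shift tests were set out before their results. Several developmental families, picked by symbol, carried the mark widely, and others did not. Only family members on the chromosomes analysed were measured. All 7 measured Lhx, 4 Dlx and 3 Irx genes were marked, as were 7 of 8 Nkx, 6 of 10 Sox and 14 of 28 Fox genes. Adjusted p ran from 3.30e-10 for Fox to 0.000293 for Irx (two-sided Fisher's exact test over 18 groups). The test counted each gene separately, so where members of a family are neighbours its p-value overstates the evidence. The signalling families Wnt and Fgf had 4 of 9 and 4 of 13 marked (adjusted p = 0.00134 and 0.00589). The shares marked of Tbx (1 of 8, adjusted p = 0.383), Bmp (2 of 8, 0.0805) and Zfp zinc finger genes (11 of 227, 0.882) did not pass; those of Gata (3 of 4, 0.00102), Pax (3 of 7, 0.00619) and Pou3 or Pou4 genes (4 of 5, 8.46e-05) did. Of 191 vomeronasal receptor genes 0 were marked (adjusted p = 7.97e-05), and of 47 ribosomal protein genes 0 (adjusted p = 0.206). MicroRNA genes had 92 of 201 marked, but their median interval is 81 bp. Genes shorter than 1000 bp were marked more often than longer ones (9.96% against 5.51%), but that share includes the microRNAs. Of 123 marked genes among the 1235 shorter ones, up to 91 were microRNAs by biotype. The share therefore does not show that short genes in general are marked more often. The cause was not tested. Coding genes on the X chromosome had 0.516 ± 0.00801 (SD, n = 4 libraries) of the autosomal median density. Input was not used, so copy number was not separated from the level of the mark there.

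The clones differed from each other far more than the times did. edgeR called 8633 intervals higher in clone A and 5132 lower, or 8090 and 7927 with each library's trend over density removed, and 603 of 19946 genes differed at least 1.5-fold. The 2 libraries of a clone are times of 1 clone, so the test describes these clones. Clone A had more of the mark at Nnat (log2 difference 1.35, SE 0.20), at Repin1 (1.21, SE 0.11), at Utf1, a pluripotency factor (1.18, SE 0.18), and at Commd7 (1.09, SE 0.07). Clone B had more at Ccl20, a chemokine gene (−1.18, SE 0.14), and at Ino80b (−1.23, SE 0.23). Mean densities in clones A and B were 0.612 and 0.243 at Nnat, 1.23 and 0.542 at Repin1, and 1.51 and 0.680 at Utf1. They were 1.37 and 0.653 at Commd7, 0.643 and 1.48 at Ccl20, and 0.140 and 0.328 at Ino80b. The median gene had 0.357, so Ino80b lay below it in both clones. Input was not used, so differences near background were not separated from the mark. These genes were named after their values were seen, and each was higher in both libraries of the clone.

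A trend over density was weighed as the source of these large differences. With genes in 10 groups by density, the median log2 difference of clone A minus clone B ran from −0.05 to 0.17. A shift of that size is smaller than 1.5-fold, so alone it falls short of these differences. With the trend removed, 1366 of the 1393 intervals called at 1.5-fold or more (98.1%) were still called, at any fold. Removing so small a trend could end few of these calls, so that share does not test it. Against gain or loss of a chromosome or a large segment, 0% of the 603 genes lay in windows of 50 consecutive genes with a median difference of 0.4 or more. The most extreme window had 0.31. A median over 50 genes cannot show a segment of far fewer genes, and input was not used, so small segments stay open. The smaller excess in clone A at 39 Hox and neuroectoderm genes is different: their median fell from 0.21 (SD 0.09 across genes, 33 called) to −0.03 (SD 0.08, 1 called higher and 3 lower) with the trend removed, in line with a higher enrichment of dense genes in clone A. Differences in culture or library batch between the clones stay open.

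A hypothesis from these values is that imprinted genes, read from 1 parental copy, may differ between the clones more often than other genes. Of 52 measured imprinted genes 6 (11.5%) differed at least 1.5-fold, against 597 of 19894 others (Fisher's exact p = 0.00466, odds ratio 4.22). They were Nnat, Blcap, Gnas, Gnasas1, Mkrn3 and Peg12. They lie in pairs: Nnat within Blcap and Gnas overlapping Gnasas1 on chromosome 2, and Mkrn3 near Peg12 on chromosome 7. The genes are therefore not independent. Of 10000 circular shifts of the list along the gene order, 0.75% held as many. At the Gnas locus (chromosome 2) clone A had more over Gnas (0.65, SE 0.05) and less over Gnasas1 (−1.32, SE 0.11), although their intervals overlap. The list was drawn up after some of these genes had been seen to differ, so neither test counts as support, and the hypothesis needs other clones.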
